A study of Xenopus tropicalis x Xenopus laevis with 26 samples.

How the data were processed

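Total RNA of hybrid embryos from X. laevis eggs fertilised with X. tropicalis sperm was measured at 13 stages, in 26 libraries, with 2 libraries per stage. Per the labels, females received 500 U and males 150 U of HCG, embryos were kept at 23 °C, and libraries were made with a NEBNext Ultra RNA kit and read as 150-base pairs on an Illumina HiSeq. The labels mention 2 biological replicates in a sentence that names seedlings, and nothing says that the replicates came from separate clutches, so p-values measure the spread between these samples, which may be technical. The submitters' notes name Trimmomatic 0.38 and STAR 2.7.9a. The genome builds, the annotation and the counting tool's version are not given in the sources used here, and the strand of the libraries is not marked.

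Each library has 1 table of genes. The expected count of each gene was estimated by the authors from aligned reads. Between 97.2% and 99.3% of the values per library, zeros included, were whole within 0.005. All were rounded to whole counts here. The TPM values, scaled for transcript length and total, were computed by the authors and deposited in the same tables per the file headers. The FPKM values, scaled for length and depth, were likewise computed by the authors and deposited per the file headers. Only expected counts were used in tests. The tables list 62288 genes, 28772 of X. tropicalis, 15751 of them with a named symbol and 10584 with a LOC name, and 33516 of X. laevis under numbered identifiers that the tables do not pair with names. Reads shared by both genomes are divided by the authors' counting. The plan took the X. tropicalis counts at S3 to S7 as a background of misassigned X. laevis reads and sperm RNA together. Errors in the other direction could not be measured here. Nor could misassigned reads of X. laevis genes that came on after S7, since this background holds only RNA present at S3 to S7.

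Samples were grouped by the stage in their labels. Counts of both parental sets were filtered with filterByExpr (minimum count 10), scaled by TMM and fitted in edgeR 4.0.16 (R 4.3.3) with a robust quasi-likelihood model with stage as the only factor, giving 37872 tested genes and 13 residual degrees of freedom. The contrasts were S7 minus S3, S9 minus S7, S12 minus S9, S24 minus S12 and S41 minus S24, the 12 pairs of neighbouring stages, and an F test over all stages. A gene was called at a two-sided Benjamini-Hochberg adjusted p under 0.05 within its contrast. Standard errors of log2 changes were derived from the F statistic. CPM is the count divided by the library total, and mean ± SD is over the 2 libraries of a stage. The biological coefficient of variation had a median of 13.6%. The total count per library was between 5928957 and 8047967, which sets the floor of 3 counts at 0.373 to 0.506 CPM. A fold against a stage without counts is given as at least the ratio to that floor, and with 1 to 3 counts in a library of the lower stage only CPM is given. Intervals and floors cover counting error only.

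The paternal share is the percent of a library's gene counts in X. tropicalis genes, with a 95% Wilson interval, tested with 100000 permutations of the stage labels. The first stage of detection is the first with at least 1 CPM in both libraries. Gene lists (24), the rule for naming genes and the alternatives were written before the data were examined. The lists are early zygotic mesendoderm, oocyte and maternal, neural plate and neurons, neural crest, skeletal muscle, heart, blood, cilia, epidermis, liver with gut and pancreas, pronephros, eye, notochord and cartilage, Hox, cell division, cohesin and chromosome loops, DNA methylation and Polycomb, transposon silencing, p53 and cell death, heat shock, sperm and testis, ribosomal proteins, mitochondrial respiration and histones. Lists with at least 5 measured genes were tested in limma 3.58.1 with camera on log-CPM (prior count 2, preset correlation 0.01) against the other X. tropicalis genes, adjusted over the lists of a contrast. S7 minus S3 was left out of list tests because almost no X. tropicalis gene of a list had counts. Named genes are, per contrast, the 8 X. tropicalis genes with the largest rise and the 4 with the largest fall among those with an adjusted p under 0.05, at least 10 CPM in the higher stage, no overlap between the libraries of the stages and a proper symbol, up to 4 members per list with the smallest p, members cited as exceptions, and the X. laevis genes with the largest changes. Fewer are printed for space.

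The alternatives were a minimum log2 change of 1, RLE factors, library totals without TMM, scaling within each parental set, other count filters, the replicate number as a block, fits of only the 4 libraries compared, leaving out each library, DESeq2 1.42.0, and for list tests an estimated correlation and fry. For the paternal share, loci detected at S3 or the 1% most abundant genes were left out, and other minimums were used for detection. Simulated data were made from the S41 and S24 libraries with known changes in some of 35580 genes. Of 100 genes changed 2-fold 28% were recovered, and of 99 changed 4-fold 76.8%, with 0 in the wrong direction and 4 of 35381 unchanged genes called. In simulated lists among 15175 X. tropicalis genes, 10 of 10 raised lists were called and 0 of 20 unchanged ones. Genes were simulated independently of each other, so this does not show how camera does with correlated genes. Few genes were changed, so these rates may differ for contrasts in which many genes changed. The ratio of parental copies of a gene was not analysed here, because X. laevis genes could not be matched by symbol, and chromatin loops were not analysed here. Python code used numpy 2.4.6, pandas 2.3.3, scipy 1.17.1 and matplotlib 3.10.9.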

Results

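RNA was sequenced from hybrid embryos made by fertilising Xenopus laevis eggs with Xenopus tropicalis sperm, so that X. tropicalis transcripts came from the paternal genome and X. laevis transcripts from the maternal one. The 26 libraries covered 13 developmental stages with 2 libraries each. Stages 3, 5 and 7 are cleavage stages, 8 and 9 blastulae, 10 to 12 gastrulae, 13 and 16 neurulae, 24 and 34 tailbud embryos and 41 a tadpole stage, written S3 to S41 here. The gene tables listed 28772 X. tropicalis genes and 33516 X. laevis genes separately. The total count per library was between 5928957 and 8047967. The series title links chromatin loops in X. tropicalis sperm with late gene expression in the embryo. The time course shows when each paternal gene first reached a set level and how it changed afterwards. Changes in single genes are from edgeR's quasi-likelihood test with Benjamini-Hochberg adjustment, and levels are in CPM, counts scaled to the total of each library, as mean ± SD over n = 2 libraries.

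X. tropicalis genes held a small share of the counts in cleavage embryos, nearly all of it in 25 loci described below, and a larger one from S9 onwards. The X. tropicalis share of all gene counts was 0.274% ± 0.0158 (SD, n = 2) at S3, 0.317% ± 0.0340 at S5, 0.294% ± 0.0221 at S7 and 0.467% ± 0.0225 at S8. It reached 4.53% ± 1.97 at S9, 19.98% ± 0.311 at S10, 32.0% ± 0.418 at S11 and 29.995% ± 0.340 at S12. It was 35.6% ± 0.923 at S13, 42.7% ± 0.346 at S16, 44.5% ± 0.0926 at S24, 41.6% ± 2.38 at S34 and 44.1% ± 0.529 at S41. A permutation test of the stage labels on the between-stage F statistic gave F = 839 and p = 1e-05 (one-sided, as F tests are), the smallest p that 100000 permutations can give. Single pairs of stages were not tested for the share. The S9 libraries stood apart from each other, at 5.92% in replicate 1 (95% Wilson interval 5.901 to 5.935) and 3.13% in replicate 2 (3.120 to 3.146). These intervals cover counting error only.

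**Figure D1:**
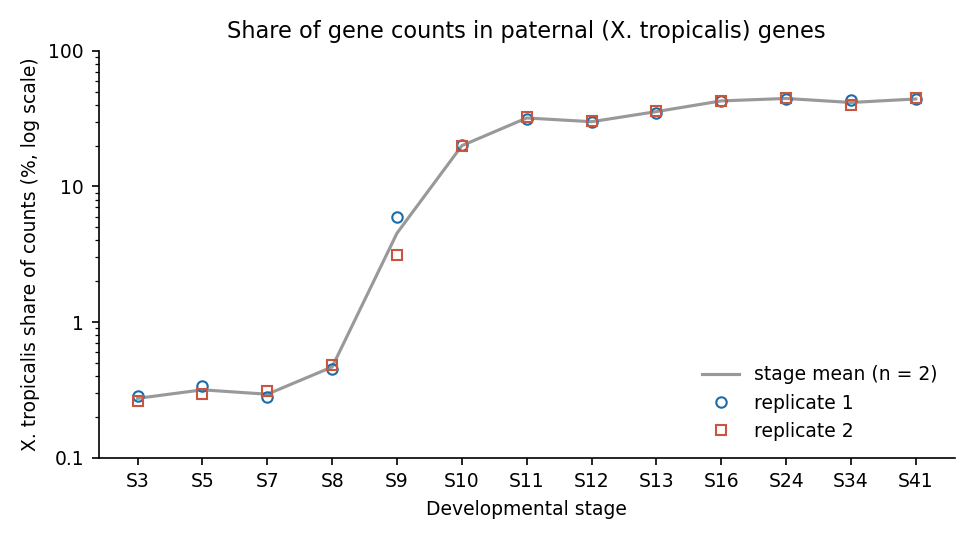
Share of all gene counts assigned to X. tropicalis (paternal) genes, in percent on a log axis, for each library by developmental stage. Circles are replicate 1, squares replicate 2 and the line joins the stage means, which rise from 0.467% at S8 to 44.5% at S24.

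Before S9, nearly all X. tropicalis counts lay in 25 loci that were already at 1 CPM or more in both S3 libraries. Of these, 20 have placeholder (LOC) names and held between 98.7% and 99.5% of the X. tropicalis counts in the 8 libraries of S3 to S8. The other 5 were the membrane calcium pump gene atp2b1, the RNA helicase gene ddx3x, marcks, mex3b and sumo3. In 15 of the 25 loci the count, rounded to a whole number, equalled that of another locus in every library, 10 of them forming a single group, so the counting could not tell these copies apart and their levels are uncertain. Outside the 25 loci, the 8 early libraries held 53 to 222 X. tropicalis counts each, a mean share of 0.00132% at S3, 0.000882% at S5, 0.00284% at S7 and 0.00146% at S8, against 3.81% at S9. The number of X. tropicalis genes with any count was 52 to 158 in these libraries and 8652 and 7212 in the S9 libraries. The X. tropicalis counts before S9 may be misassigned X. laevis reads, sperm RNA or early transcription, which cannot be told apart here.

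Paternal genes were first detected over many stages, and the counts per stage differed between gene lists, which no test compared. Of 15480 X. tropicalis genes that reached 1 CPM in both libraries of some stage, 2155 (13.9%) did so first at S9, 3736 (24.1%) at S10, 1984 (12.8%) at S11, 877 at S12, 1004 at S13 and 2152 (13.9%) at S16. Another 3546 genes (22.9%) were first detected at S24 or later, 1058 of them at S24, 1464 at S34 and 1024 at S41. Genes of the early mesendoderm list, which holds germ layer regulators such as eomes, lefty and ventx1.1, were mostly first detected at S9 (39 of 43). Of 76 ribosomal protein genes, 23 were first detected at S9 and 52 at S10, and of 36 cohesin and chromosome loop genes 16 at S9 and 17 at S10. Of 49 cell division genes, 26 were first detected at S9 and 15 at S10. Respiration genes were spread more widely, with 5 of 81 at S9, 24 at S10, 25 at S11, 8 at S13 and 12 at S16. Hox genes, which pattern the head-to-tail axis, were spread over S11 (10 of 36), S12 (8), S13 (4) and S16 (8). Skeletal muscle genes were most often first detected at S16 (12 of 36). Many organ genes were detected late, with 25 of 35 eye genes (9 at S34 and 16 at S41), 18 of 35 liver, gut and pancreas genes (12 at S34 and 6 at S41) and 12 of 26 blood genes (6 at S34 and 6 at S41) first detected at the final 2 stages. Other organ genes were earlier, with 8 of 25 pronephros, 9 of the 35 liver, gut and pancreas and 12 of 41 neural genes at S9 or S10. The minimum sets the size of the first wave. At 5 CPM, 766 genes were first detected at S9. The floor of 3 counts was 0.373 to 0.506 CPM per library, so a gene below the minimum may hold counts and was not shown to be absent. At 0.5 CPM, 3127 genes were first detected at S9. The test of single genes called 5091 X. tropicalis genes higher at S9 than at S7. Many genes dated to S10 or later were therefore already measured at S9. Both libraries had to pass, and S9 replicate 2 had a paternal share of 3.13% against 5.92% in replicate 1.

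**Figure D2:**
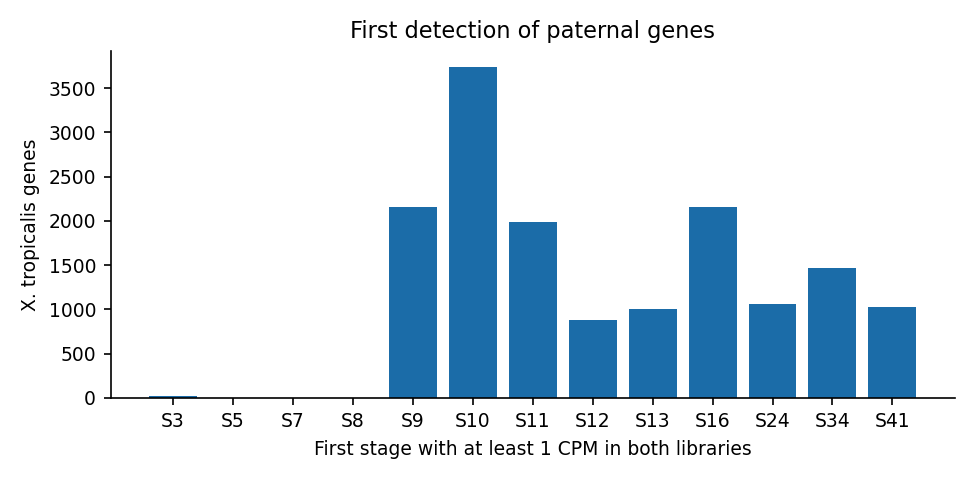
Number of X. tropicalis genes by the first stage at which both libraries held at least 1 CPM. Bars rise from 2155 genes at S9 to 3736 at S10, and a later bar of 2152 genes stands at S16.

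**Figure D3:**
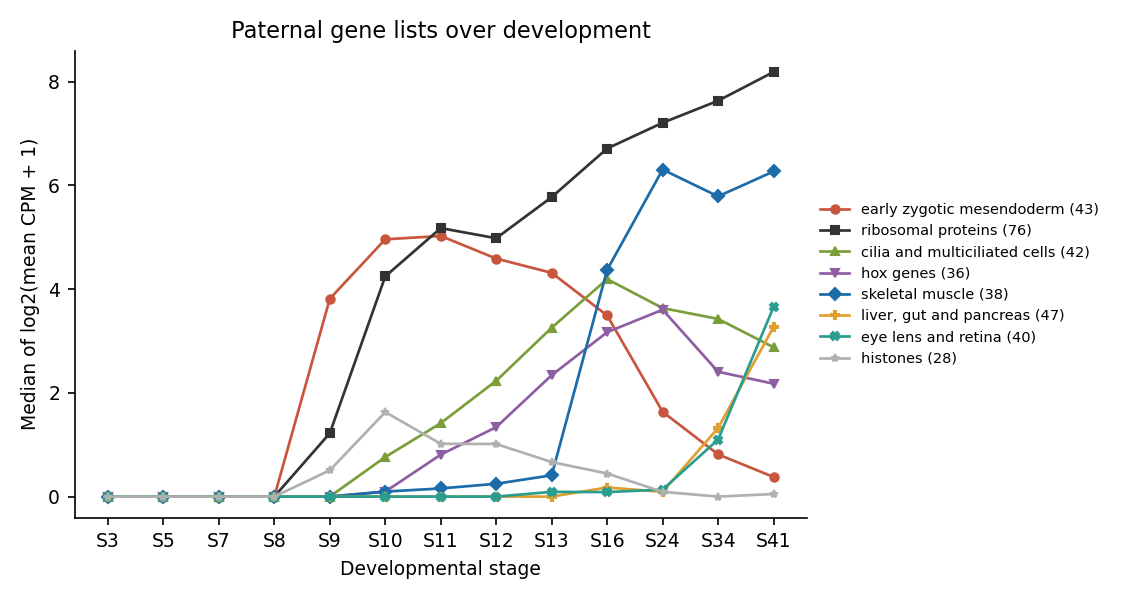
Median over the X. tropicalis members of 8 gene lists of log2(mean CPM + 1), by stage, with the number of members in the tables in brackets. The early mesendoderm line leads at S9 with a median of 3.82, while the eye line stays near 0 until S24 and reaches 3.66 at S41.

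Between S3 and S7, many maternal transcripts changed, while few paternal genes had enough counts to be compared. These stages were chosen as preceding zygotic transcription, though a few early mesendoderm counts at S7, described below, leave that open for S7. Of 22697 X. laevis genes tested, 5115 rose and 4661 fell. The gene listed as gene21398 rose from 0 to 46.1 CPM and gene4954 fell from 115 to 0.0669 CPM. The tables do not pair X. laevis identifiers with gene names. Few X. tropicalis genes had counts that could change. A fit of only the 4 libraries compared tested 25 X. tropicalis genes and called 1 higher and 12 lower. Of 15175 X. tropicalis genes in the fit of all libraries, 2 rose and 11 fell. That split was 6 and 1 with library totals, so no direction is read from it. The 2 that rose were LOC116412363, by 1.46 ± 0.28 (SE) on the log2 scale (edgeR adjusted p = 0.0007), and klf17, with 3 and 5 counts at S7 and 0 in both S3 libraries (adjusted p = 0.047). Those that fell were the 10 loci with equal counts, at -0.49 ± 0.12 (edgeR adjusted p = 0.0025), and rap1b, from 4 and 10 counts to 0 (adjusted p = 0.0014). These 13 are named because so few were called, chosen after the values were seen. The klf17 call was lost without any single library of the 4. It was also lost with the replicate number as a block (edgeR adjusted p = 0.058), with RLE factors (edgeR adjusted p = 0.086) and by DESeq2 (adjusted p = 0.052). DESeq2, run on both parental sets together with its own scaling, called 16 X. tropicalis genes. Scaled within their own set, 0 X. tropicalis genes were called by edgeR, with 18 higher and 1 lower at an unadjusted p under 0.05. Without S3 replicate 1 there were 3 calls and without S7 replicate 1 there were 4. The X. laevis split was 7330 higher and 3020 lower when libraries were scaled by total count alone, 4260 and 5405 with RLE factors, 4896 and 5585 within the set and 4417 and 5622 by DESeq2, so no direction is read from it. Among X. laevis genes, 19 stood at 5 CPM or more in S3 replicate 2 and under 0.5 CPM in replicate 1, with 0 the other way round. Replicates with the same number deviated together between S3 and S5 (r = 0.522) but not between S3 and S7 (r = 0.034). The labels do not name females, so a difference between egg batches cannot be told apart from stage in the changes from S3 to S7.

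From S7 to S9, across the midblastula transition, the paternal genome went from near silence to broad expression. Of 15175 X. tropicalis genes, 5091 rose. Among genes with a proper symbol, the largest rises were in pnrc2, a nuclear receptor coactivator gene, at 425 ± 166 CPM in S9 (at least 1040-fold higher, log2 change 14.66 ± 0.49 SE, edgeR adjusted p = 1.2e-12), and in eef1a1o, an oocyte-type translation elongation factor, at 349 ± 252 CPM (at least 852-fold higher). They were followed by the histone variant gene h3-3b (at least 702-fold higher), the T-box gene vegt (at least 631-fold), sp5l (at least 605-fold), anp32c (at least 571-fold) and the splicing factor genes srsf2 (at least 484-fold) and hnrnpa2b1 (at least 463-fold). All 8 had no count at S7, and the folds are against a floor of 3 counts per library. The germ layer regulators rose together. In the early mesendoderm list, 40 of 43 genes rose, among them the Nodal antagonist gene lefty (51.1 ± 10.3 CPM at S9), fgf8 (20.7 ± 5.9027 CPM), eomes (179 ± 84.7 CPM) and ventx1.1 (46.3 ± 20.4 CPM), all without a count at S7. The list was higher than other X. tropicalis genes by limma's camera test (adjusted p = 1.8e-21, and adjusted p = 0.088 with an estimated correlation).

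Genes of the cell cycle and of chromosome structure rose with them. Of 48 cell division genes 38 rose, among them cdc25b, the phosphatase that activates mitotic kinases (35.7 ± 2.14 CPM), the replication licensing inhibitor gmnn (103 ± 40.1 CPM) and the cyclin gene ccne2 (102 ± 43.3 CPM), with a camera adjusted p of 1.3e-11 (adjusted p = 0.31 with an estimated correlation). Of 36 genes for cohesin and chromosome loops 29 rose (adjusted p = 3.7e-09, and adjusted p = 0.34 with an estimated correlation), including the insulator protein gene ctcf (28.3 ± 15.6 CPM), the cohesin acetyltransferase esco2 (7.02 ± 3.85 CPM) and the cohesin release factor wapl (4.98 ± 2.73 CPM). Ribosomal protein genes were raised at low level, with 59 of 76 higher (adjusted p = 1.6e-10, and adjusted p = 0.35 with an estimated correlation), including rpl3 at 9.60 ± 3.78 CPM. Histone genes followed with 15 of 17 (adjusted p = 4.5e-05, and adjusted p = 0.29 with an estimated correlation). Stress lists were raised as well. Of 27 p53 and cell death genes 15 rose (adjusted p = 0.0036, and adjusted p = 0.35 with an estimated correlation), including tp53inp1 (62.3 ± 20.7 CPM) and gadd45a (23.039 ± 5.74 CPM). Of 27 heat shock and unfolded protein genes 17 rose (adjusted p = 0.0011, and adjusted p = 0.35 with an estimated correlation), including herpud1 (45.7 ± 15.6 CPM) and xbp1 (59.9 ± 26.3 CPM), which encode parts of the endoplasmic reticulum stress response.

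The lists of tissue genes differed in how many members rose. Of 30 epidermis genes 18 rose, such as the ionocyte regulator foxi4.2 (81.5 ± 29.6 CPM) and the cadherin gene cdh1 (18.3 ± 8.25 CPM), with a camera adjusted p of 0.0015 (adjusted p = 0.34 with an estimated correlation). Of 22 neural crest genes 12 rose, such as tfap2a (99.6 ± 49.5 CPM) and tfap2c (60.7 ± 30.9 CPM), with an adjusted p of 0.045 that became 0.13 when X. tropicalis genes were scaled within their own set, and an adjusted p = 0.35 with an estimated correlation. The neural list gave no call in limma's camera (adjusted p = 0.19), with 16 of 41 genes higher, including sox11 (46.9 ± 15.4 CPM) and zic2 (21.9 ± 4.34 CPM). Of 16 oocyte and maternal genes 10 rose (adjusted p = 0.01, and adjusted p = 0.34 with an estimated correlation). Of the 40 X. tropicalis genes of this list, only 17 were detected at any stage. Those never detected include zar1, zp2, gdf9, figla and nobox. Those first detected at S9 include plk1 and cdc20, which are also in the cell division list. At the other end, 2 of 35 skeletal muscle genes rose, and the list lay below other genes (adjusted p = 0.019, and adjusted p = 0.31 with an estimated correlation). The same held for the eye list, where 2 of 35 rose (adjusted p = 0.012, and adjusted p = 0.088 with an estimated correlation), the retinal regulator crx (15.7 ± 10.3 CPM) and the G protein subunit gnb1 (7.03 ± 5.63 CPM). It also held for Hox genes, with 5 of 36 higher (adjusted p = 0.045, and adjusted p = 0.31 with an estimated correlation), including hoxd1 at 2.39 ± 1.61 CPM, and for blood genes, with 4 of 26 higher, including gata2 at 33.3 ± 33.4 CPM (adjusted p = 0.045, and adjusted p = 0.35 with an estimated correlation). Cilia genes (12 of 42 higher, including ccno at 17.4 ± 2.6969 CPM and rfx2 at 29.1 ± 18.9 CPM), notochord and cartilage genes (5 of 20, including foxa4 at 57.8 ± 31.991 CPM), pronephros genes (13 of 24) and Polycomb and DNA methylation genes (13 of 22, including suz12 at 6.24 ± 2.35 CPM) gave no camera call, at adjusted p values of 0.45, 0.78, 0.61 and 0.077. Nor did heart (1 of 16), liver and gut (6 of 34), transposon silencing (6 of 11), sperm (1 of 8, ropn1l at 77.2 ± 41.6 CPM) and mitochondrial respiration genes (25 of 80), at 0.059, 0.11, 0.45, 0.37 and 0.82. Adjusted over the list alone, the numbers that rose were 40 for cell division, 31 for cohesin, 60 for ribosomal, 16 for p53, 4 for Hox, 2 for blood and 5 for liver and gut genes, and those given above for the other lists.

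In the test of single genes, 0 X. tropicalis genes fell from S7 to S9 by edgeR, also 0 at an unadjusted p under 0.05 (1 within the set) and 0 by DESeq2. Only 131 and 158 X. tropicalis genes had any count in the S7 libraries, so few could fall. The S9 replicates differed in paternal share, and 648 of 700 X. tropicalis genes at 10 CPM or more in S9 were higher in replicate 1. A fit of only the 4 libraries compared called 1751 of the 1774 X. tropicalis genes that passed its filter. The median X. tropicalis log2 change was 2.39, and 5.37 when scaled within the set. It was 1.77 with RLE factors and 2.63 without S9 replicate 2. It was 0 without S9 replicate 1, with no low-count filter and by DESeq2. Each of the settings at 0 took in more genes, but so did the fit without S9 replicate 2. The number of genes taken in thus does not by itself give a median of 0. Among X. laevis genes 7989 rose and 2325 fell, a split that was 4979 and 3984 with RLE factors, 4858 and 4171 with library totals, 6090 and 3447 within the set and 5193 and 4251 by DESeq2. Without S7 replicate 1 it was 3488 and 3256. The largest changes were in gene4771, from 0 to 172 CPM, and gene19835, from 84.3 CPM to 0.

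From S9 to S12, through gastrulation, most paternal genes tested rose relative to all genes, and early mesendoderm genes lost ground relative to the other paternal ones. Of 15175 X. tropicalis genes 9573 rose and 185 fell. The largest rises, each from no count at S9, were in the complement genes c3 (389 ± 57.1 CPM at S12, at least 926-fold higher, log2 change 14.68 ± 0.65 SE, edgeR adjusted p = 4.9e-09), cfh (at least 293-fold) and c9 (at least 273-fold), the gap junction gene gjb1 (at least 531-fold), otogl2 (at least 248-fold), the growth factor gene igf2 (at least 209-fold), tuba1cl.3 (at least 185-fold) and the presomitic mesoderm regulator tbx6 (at least 168-fold). The largest falls included genes of early mesendoderm induction. The homeobox gene bix1.2 went from 18.9 ± 2.92 CPM to no count (at least 42.7-fold lower), nodal3.1 from 22.6 ± 3.46 CPM to 0.428 ± 0.148 CPM, nodal6 from 12.6 ± 2.31 CPM to 0.414 ± 0.357 CPM and the kinase gene sbk1l from 39.7 ± 8.58 CPM to 1.84 ± 1.92 CPM. The bix1.2 and nodal3.1 calls were not made by DESeq2 (adjusted p = 0.38 and 0.67). Because the paternal share itself grew, counts are given below first relative to all genes and then scaled within the X. tropicalis set. The 2 scalings put the median X. tropicalis log2 change at 3.45 and 0.76, and within the set 2677 genes rose and 1631 fell. Left out singly, S9 replicates 1 and 2 and S12 replicates 1 and 2 brought the 185 that fell to 95, 104, 79 and 89.

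Early mesendoderm genes went down relative to the rest of the paternal genome, though the list median of log2(mean CPM + 1) was 3.82 at S9 and 4.59 at S12. Of 43 genes 20 rose and 12 fell, and within the set 2 rose and 36 fell. The list lay below other X. tropicalis genes (camera adjusted p = 1.1e-08, and adjusted p = 0.33 with an estimated correlation). lefty fell 9.06-fold to 5.64 ± 1.82 CPM and eomes from 179 ± 84.7 CPM to 27.6 ± 3.01 CPM. Histone genes showed 6 of 17 higher and 1 lower, and 1 and 11 within the set, with a lower list (adjusted p = 0.0059, and adjusted p = 0.43 with an estimated correlation). The neural list was also lower relative to other genes (adjusted p = 0.0013, and adjusted p = 0.33 with an estimated correlation), with 16 of 41 higher and 3 lower, and 3 and 15 within the set. Its members that rose most clearly were the neuronal RNA-binding protein gene elavl3 (35.5 ± 8.83 CPM) and myt1 (19.953 ± 2.67 CPM). Ribosomal protein genes rose as a block, 76 of 76 and 56 within the set, with rpsa at 48.5 ± 0.145 CPM and rpl19 at 51.2 ± 1.77 CPM (adjusted p = 2.1e-10, and adjusted p = 0.6 with an estimated correlation). Cilia genes rose in 37 of 42, 14 of them higher and 2 lower within the set (adjusted p = 0.0059, and adjusted p = 0.5 with an estimated correlation), including the master regulators of ciliated cells foxj1 (41.3-fold higher, at 51.9 ± 8.98 CPM) and mcidas (20.2 ± 3.15 CPM).

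For 5 other tissue lists, camera gave no call against the other X. tropicalis genes. Their shares of members that rose were not tested against the 9573 of all 15175 genes that rose. Of 30 epidermis genes 24 rose (12 higher and 5 lower within the set), such as dlx3 (63.5 ± 3.02 CPM), the keratin gene krt19 (29.2 ± 0.275 CPM) and tp63 (28.8 ± 6.73 CPM). Of 22 neural crest genes 17 rose (5 and 6), such as msx1 (89.2 ± 15.5 CPM) and pax3 (17.6 ± 0.297 CPM). Of 35 muscle genes 14 rose (9 and 1), including the giant sarcomere protein gene ttn (96.2 ± 2.57 CPM) and the muscle determination gene myf5 (27.9 ± 6.15 CPM). Of 34 liver and gut genes 13 rose and 1 fell (6 and 2), including the intestinal regulator cdx2 (195 ± 11.6 CPM) and the endodermal gene darmin (106 ± 2.85 CPM). Of 36 Hox genes 23 rose (7 and 3). None of these 5 lists had a camera call, at adjusted p values of 0.061, 0.3, 0.36, 0.061 and 0.42. Cohesin and chromosome loop genes rose in 34 of 36 (14 and 3 within the set), with the cohesin ring genes smc3 at 56.0 ± 2.12 CPM and smc1a at 71.5 ± 6.73 CPM. Their list call (adjusted p = 0.00023) was lost within the set (adjusted p = 0.59, and adjusted p = 0.61 with an estimated correlation). The calls were likewise lost for cell division genes, of which 42 of 48 rose (8 and 12 within the set), including fzr1 (27.7 ± 0.244 CPM). Their adjusted p was 0.013, 0.065 within the set and 0.61 with an estimated correlation. Mitochondrial respiration genes rose in 61 of 80 (9 and 2), with adjusted p values of 0.038, 0.23 within the set and 0.61 with an estimated correlation. Polycomb and DNA methylation genes rose in 18 of 22 (8 and 2), including the histone demethylase kdm6b (100 ± 11.7 CPM) and jarid2 (61.5 ± 7.91 CPM), without a camera call (limma, adjusted p = 0.062).

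Some organ lists lay below other genes in this scaling. The eye list lay below other genes (adjusted p = 0.00023, and adjusted p = 0.011 with an estimated correlation), a call lost within the set (adjusted p = 0.34), with 10 of 35 genes higher (2 and 2 lower within the set). Blood genes (7 of 26 higher, 1 and 3 lower within the set, among them lmo2 at 13.6 ± 0.0923 CPM) and heart genes (6 of 16 higher and 1 lower, 1 and 1 within the set, actc1 at 64.6 ± 13.1 CPM) had adjusted p values of 0.0013 and 0.044. Those calls ended within the set (adjusted p = 0.59 and 0.93) and with an estimated correlation (adjusted p = 0.33 and 0.43). The gene actc1 is in the skeletal muscle list as well. No call was made for the pronephros list (12 of 24 higher, 2 and 7 lower within the set), oocyte list (11 of 16 higher and 1 lower, 3 and 3 within the set, gdf3 falling to 19.3 ± 1.72 CPM), or notochord list (11 of 20 higher and 1 lower, 5 and 3), at limma adjusted p values of 0.15, 0.84 and 0.59. Nor was one made for the transposon silencing (10 of 11 higher, 5 and 1 lower within the set), sperm (6 of 8, 1 and 1), p53 (19 of 27 and 1 lower, 3 and 8) or heat shock list (23 of 27, 9 and 6), at 0.3, 0.84, 0.84 and 0.069. Adjusted over the list alone, the numbers that rose were 24 for Hox, 43 for cell division, 64 for mitochondrial, 15 for neural (with 2 lower), 5 for blood and 7 for eye genes, and those given above for the other lists. Among X. laevis genes 3803 rose and 10757 fell. That split turned to 7792 and 6076 with RLE factors, 7566 and 6347 within the set, 7836 and 5969 by DESeq2, and 6743 and 6515 without S9 replicate 1, with like splits without each other library of the pair, so no direction is read from it. The largest changes were in gene24441, from 0 to 1071 CPM, and gene31233, from 113 to 0.0666 CPM.

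From S12 to S24, from the late gastrula to the tailbud embryo, contractile muscle genes came on strongly and early mesendoderm genes fell. Of 15175 X. tropicalis genes 8440 rose and 1688 fell, and within the set 5657 rose and 3570 fell. The largest rises, each from no count, were in the skeletal myosin heavy chain genes myh8 (1521 ± 35.9 CPM at S24, at least 3440-fold higher, log2 change 16.31 ± 0.33 SE, edgeR adjusted p = 1.6e-15), myh4 (1126 ± 46.8 CPM) and myh2 (515 ± 23.024 CPM), klhl31 (at least 366-fold), the lipoprotein gene apoe (at least 345-fold), the epidermal lectin gene itln1 (at least 291-fold), the muscle enzyme gene pgam2 (at least 268-fold) and the troponin gene tnnc1 (at least 262-fold). The largest falls were in the Nodal co-receptor gene tdgf1.3, from 20.6 ± 4.02 CPM to no count (at least 52.0-fold lower), cd36 (at least 35.1-fold lower), the histone gene h3c14 (at least 31-fold lower) and the Nodal and Wnt antagonist cer1, from 91.6 ± 3.72 CPM to 0.263 ± 0.000606 CPM. The h3c14 call (edgeR adjusted p = 0.023) was lost without either library of S12 or S24, at adjusted p values of 0.055 to 0.097.

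Early mesendoderm genes fell in 31 of 43 cases (40 within the set), and the list call held with an estimated correlation (camera adjusted p = 6.1e-27, and adjusted p = 0.033 with an estimated correlation). ventx1.1 fell from 109 ± 9.12 CPM to 12.442 ± 1.18 CPM, wnt8a from 43.8 ± 4.18 CPM to 6.72 ± 0.947 CPM and eomes from 27.6 ± 3.01 CPM to 0.724 ± 0.0948 CPM. Histone genes fell in 9 of 17 (13 within the set), including the linker histone h1-1 from 81.6 ± 8.66 CPM to 15.208 ± 0.989 CPM (adjusted p = 3.3e-08, and adjusted p = 0.049 with an estimated correlation). Skeletal muscle genes rose in 27 of 35 with 1 lower, the same counts within the set (adjusted p = 9.6e-08, and adjusted p = 0.024 with an estimated correlation). The fast myosin light chain mylpf rose 128-fold to 512 ± 15.6 CPM, the troponin gene tnnt3 424-fold to 278 ± 21.3 CPM, and creatine kinase ckm to 101 ± 3.58 CPM. Hox genes rose in 34 of 36 (26 within the set), with hoxa3 at 33.1 ± 2.50 CPM, hoxc4 at 43.1 ± 6.06 CPM and hoxd10 at 14.6 ± 1.08 CPM (adjusted p = 0.00069, and adjusted p = 0.045 with an estimated correlation). Of all Hox genes only hoxd1 fell, from 43.3 ± 1.88 CPM to 10.3 ± 0.676 CPM.

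Cilia genes moved in both directions. The commitment factors ccno and mcidas fell from 16.6 ± 4.62 CPM to 0.198 ± 0.0936 CPM and from 20.2 ± 3.15 CPM to 0.263 ± 0.186 CPM, and foxj1 from 51.9 ± 8.98 CPM to 8.23 ± 0.112 CPM, while the axonemal gene tekt2 rose to 51.1 ± 2.17 CPM. In all 27 of 42 cilia genes rose and 6 fell (20 and 9 within the set), without a camera call (limma, adjusted p = 0.9). Neural genes were higher in 26 of 41 cases and lower in 6 (24 and 10), also without a camera call (limma, adjusted p = 0.34). Those that rose included nrp1 (24.7-fold higher), the neuronal tubulin tubb3 (40.1 ± 3.35 CPM) and the neurogenic factor ebf2 (21.5 ± 2.37 CPM). Neural crest genes (13 of 22 higher and 3 lower, 8 and 6 within the set) included sox10 at 46.6 ± 7.90 CPM and snai2 at 43.7 ± 8.28 CPM. Notochord and cartilage genes (12 higher and 4 lower of 20, 11 and 4) included the collagen gene col2a1, which rose from 0.361 ± 0.0543 CPM to 509 ± 44.7 CPM. Epidermis genes (16 and 7 of 30, 14 and 13) included the larval keratin krt12.4 at 310 ± 53.1 CPM and carbonic anhydrase ca2 at 58.5 ± 10.7 CPM. Blood genes (9 and 1 of 26, 8 and 2) included the myeloid enzyme mpo at 43.0 ± 5.02 CPM and tal1 at 16.5 ± 4.43 CPM. Pronephros genes were split 13 and 1 of 24 (6 and 6). Heart genes (9 of 16 higher, 8 within the set) included the cardiac actin actc1, also in the skeletal muscle list, at 1940 ± 15.1 CPM. None of these 6 lists had a call, at limma adjusted p values of 0.83, 0.83, 0.63, 0.83, 0.9 and 0.35. Nor did liver and gut (9 higher and 5 lower, 8 and 6 within the set), eye (8 and 1, 6 and 2), sperm (7 and 1 of 8, 5 and 1), transposon silencing (2 and 3, 1 and 4) and Polycomb and DNA methylation genes (12 and 2, 5 and 8, among them tet2 at 26.1 ± 2.02 CPM).

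Cell division genes lost ground, with 16 higher and 18 lower of 48, and 8 and 32 within the set (adjusted p = 1.7e-05, and adjusted p = 0.56 with an estimated correlation). gmnn fell from 76.6 ± 7.9963 CPM to 20.7 ± 0.0454 CPM and ccne2 from 108 ± 0.482 CPM to 19.2 ± 0.0442 CPM, while the spindle checkpoint gene bub1b rose 19.9-fold. Cohesin genes were split 9 to 9 of 36, and 6 to 26 within the set, esco2 falling to 29.6 ± 0.627 CPM (adjusted p = 0.0014, and adjusted p = 0.64 with an estimated correlation). The p53 list (5 higher and 11 lower of 27, 2 and 14 within the set) was lower than other genes (adjusted p = 0.00022, and adjusted p = 0.36 with an estimated correlation), with gadd45a down to 12.9 ± 0.343 CPM. So was the heat shock list (8 and 8 of 27, 5 and 16), with xbp1 falling from 265 ± 30.988 CPM to 56.1 ± 5.27 CPM and hspa1b to 0.790 ± 0.00182 CPM (adjusted p = 0.0042, and adjusted p = 0.56 with an estimated correlation). The oocyte list (6 and 6 of 16, 3 and 8) had an adjusted p of 0.025 (adjusted p = 0.53 with an estimated correlation). Ribosomal protein genes rose further in 74 of 76 (63 within the set), rplp0 reaching 395 ± 55.7 CPM (adjusted p = 0.0013, and adjusted p = 0.73 with an estimated correlation). Respiration genes rose in 67 of 80 with 1 lower (48 and 6 within the set), including the ATP synthase subunit atp5f1c at 42.4 ± 1.9598 CPM (adjusted p = 0.0014, and adjusted p = 0.53 with an estimated correlation). Adjusted over the list alone, the numbers that rose and fell were 35 and 1 for Hox, 17 and 18 for cell division, 9 and 8 for cohesin, 14 and 3 for Polycomb and DNA methylation, and 16 and 8 for epidermis genes. They were 7 and 1 for eye, 13 and 4 for notochord and 1 and 3 for transposon silencing genes, 75 rose for ribosomal genes, and the other lists kept the numbers above. The median X. tropicalis log2 change was 1.54, and 0.58 within the set. With all libraries, the 1688 X. tropicalis genes that fell were 1010 with RLE factors, 923 by DESeq2 and 1200 with library totals. Leaving out any single library of S12 or S24 lowered this number as well, and put the median X. tropicalis log2 change at 1.95 to 2.17. Those fits took in more genes and were scaled anew. Among X. laevis genes 6602 rose and 7969 fell, which turned to 8864 and 5905 with RLE factors, 8126 and 6527 with library totals and 8389 and 5879 by DESeq2, so no direction is read from it. The largest changes were in gene27109, from 0 to 1251 CPM, and gene33062, from 788 CPM to 0.

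**Figure D4:**
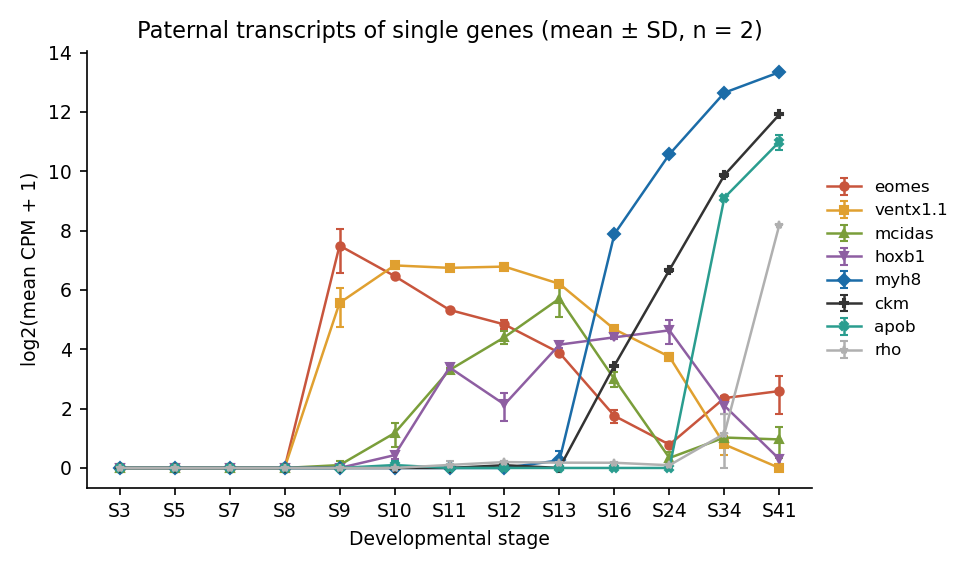
Level of 8 X. tropicalis genes by stage, as log2(mean CPM + 1), with error bars from the mean minus 1 SD to the mean plus 1 SD of the CPM (n = 2). eomes and ventx1.1 are highest between S9 and S12, mcidas at S13, hoxb1 at S24, and myh8, ckm, apob and rho at S41.

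From S24 to S41, as the tadpole formed, the eye and liver lists lay above other paternal genes and the Hox list below them. Of 15175 X. tropicalis genes 4848 rose and 3635 fell, 4728 and 3539 within the set and 3284 and 3402 by DESeq2, so no direction is read from it. The largest rises, each from no count at S24, were in the lipoprotein gene apob (2038 ± 362 CPM at S41, at least 5160-fold higher, log2 change 16.77 ± 0.36 SE, edgeR adjusted p = 3.3e-15), the retinol carrier rbp4 (959 ± 78.8 CPM), the globin gene hba4 (at least 979-fold), the fibrinogen gene fga (at least 500-fold), the keratin gene krt62 (at least 455-fold), the fibrinogen gene fgg (at least 359-fold), the keratin gene krt15.2 (at least 287-fold) and apoa4 (at least 263-fold). DESeq2 did not call hba4 or fga (adjusted p = 0.11 and 0.14). The largest falls, each to no count, were in the angiopoietin genes angpt4.2 (at least 318-fold lower) and angpt4 (at least 180-fold) and the metalloproteinase genes astl2c (at least 120-fold) and tll2l (at least 117-fold).

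Several organ lists lay above other genes, and the eye and liver calls held with an estimated correlation. Of 35 eye genes 30 rose and 3 fell (camera adjusted p = 2.3e-13, and adjusted p = 2e-05 with an estimated correlation), with the rod photopigment gene rho at 292 ± 0.927 CPM, the lens crystallin cryba1 at 67.3 ± 10.3 CPM and the cone opsin opn1lw at 49.964 ± 2.17 CPM. Of 34 liver, gut and pancreas genes 25 rose and 6 fell (adjusted p = 1.5e-07, and adjusted p = 0.00064 with an estimated correlation), with apoa1 rising 821-fold to 2217 ± 122 CPM and fetub 193-fold. Of 36 Hox genes 4 rose and 29 fell (adjusted p = 1.3e-08, and adjusted p = 0.0011 with an estimated correlation). hoxb1 fell from 23.9 ± 6.93 CPM to 0.229 ± 0.123 CPM, hoxb8 fell 22.8-fold and hoxb9 fell from 18.8 ± 2.18 CPM to 1.51 ± 0.322 CPM. Blood genes rose in 19 of 26 and fell in 4, with the globins hbe1 at 239 ± 50.4 CPM and hba-l5 at 327 ± 63.8 CPM and the red cell spectrin sptb 19.8-fold higher, while the blood progenitor gene lmo2 fell to 7.75 ± 0.915 CPM (adjusted p = 9.4e-06, and adjusted p = 0.077 with an estimated correlation). Muscle genes rose in 26 of 35 and fell in 5, ckm reaching 3852 ± 67.7 CPM and tnni2 929 ± 16.6 CPM (adjusted p = 0.00031, and adjusted p = 0.056 with an estimated correlation). Heart genes rose in 10 of 16 and fell in 2, including mybpc3 at 380 ± 30.1 CPM and the atrial light chain myl7 at 15.6 ± 3.15 CPM (adjusted p = 0.0091, and adjusted p = 0.18 with an estimated correlation). DESeq2 did not call myl7 (adjusted p = 0.32). Respiration genes rose in 71 of 80, with atp5if1 26.7-fold and sdha 19.3-fold higher (adjusted p = 3.2e-11, and adjusted p = 0.056 with an estimated correlation). Ribosomal protein genes rose in 71 of 76, rplp0 to 1116 ± 24.7 CPM (adjusted p = 9.4e-06, and adjusted p = 0.57 with an estimated correlation).

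Several other lists lay below the rest of the X. tropicalis genes. Early mesendoderm genes fell in 20 of 43 and rose in 1, with tbx6 down to 0.450 ± 0.0329 CPM and ventx1.1 from 12.442 ± 1.18 CPM to no count (adjusted p = 2.6e-07, and adjusted p = 0.2 with an estimated correlation). Epidermis genes fell in 21 of 30 and rose in 3, krt19 from 206 ± 32.6 CPM to 47.2 ± 7.87 CPM and cdh1 from 386 ± 2.84 CPM to 101 ± 6.11 CPM (adjusted p = 2.8e-05, and adjusted p = 0.2 with an estimated correlation). Cilia genes fell in 22 of 42 and rose in 3, including the dynein assembly gene zmynd10 down to 2.93 ± 0.320 CPM (adjusted p = 0.00031, and adjusted p = 0.2 with an estimated correlation). Cell division genes fell in 19 of 48 and rose in 3, ccne1 to 4.93 ± 0.0628 CPM (adjusted p = 0.0021, and adjusted p = 0.57 with an estimated correlation). Cohesin genes fell in 13 of 36 and rose in 1, pds5a to 39.5 ± 1.14 CPM (adjusted p = 0.0058, and adjusted p = 0.62 with an estimated correlation). Of 8 sperm and testis genes 5 fell, including the meiosis gene sycp1 from 71.1 ± 7.47 CPM to 0.450 ± 0.0329 CPM (adjusted p = 0.0011, and adjusted p = 0.029 with an estimated correlation). Of 16 oocyte genes 7 fell (adjusted p = 0.0095, and adjusted p = 0.3 with an estimated correlation), some of them also members of the cell division list, and of 11 transposon silencing genes 6 fell (adjusted p = 0.012, and adjusted p = 0.3 with an estimated correlation). The germ cell helicase ddx4, a member of both, fell from 34.9 ± 4.74 CPM to 1.64 ± 0.0916 CPM, and tdrd6 to 6.84 ± 1.03 CPM.

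No list call was made for neural genes (19 higher and 15 lower of 41), where genes of mature neurons such as nefm (49.0 ± 2.31 CPM) and stmn2 (42.7 ± 3.43 CPM) rose and the progenitor gene sox3 fell to 12.9 ± 3.16 CPM. Nor was one made for neural crest genes (6 and 11 of 22), where the melanin genes pmel (114 ± 5.88 CPM), tyrp1 (84.1 ± 2.44 CPM) and dct (46.6 ± 3.47 CPM) rose. The pronephros (8 and 10 of 24, slc4a4 at 36.8 ± 1.31 CPM and pax8 falling to 1.13 ± 0.188 CPM), notochord and cartilage (12 and 4 of 20, the cartilage gene epyc at 16.9 ± 0.884 CPM) and Polycomb and DNA methylation lists (5 and 10 of 22, dnmt3a at 86.5 ± 1.19 CPM) also gave none. The p53 (11 and 6 of 27), heat shock (9 and 3 of 27, hspd1 at 208 ± 14.1 CPM) and histone lists (2 and 4 of 17) gave none either. Their adjusted p values were between 0.14 and 0.8 (limma). Adjusted over the list alone, the numbers that rose and fell were 1 and 19 for early mesendoderm, 19 and 18 for neural, 26 and 7 for muscle, 4 and 21 for epidermis and 5 and 29 for Hox genes. They were 2 and 17 for cell division, 1 and 3 for cohesin, 5 and 11 for Polycomb and DNA methylation, 8 and 3 for heat shock and 2 and 3 for histone genes. For ribosomal and respiration genes 72 and 73 rose, and the other lists kept the numbers above. Globin, keratin, myosin, actin, histone and ribosomal protein genes have near-identical copies within and between the parental genomes, so the levels of single members are uncertain. Among X. laevis genes 7590 rose and 5933 fell, with gene24871 rising from 0 to 613 CPM and gene13273 falling from 373 to 0.0789 CPM.

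The number of genes that changed differed widely between pairs of neighbouring stages. Over both parental sets it was 699 from S3 to S5, 7805 from S5 to S7, 6952 from S7 to S8 and 11802 from S8 to S9. It rose to 17992 from S9 to S10 and 16652 from S10 to S11, then was 10213 from S11 to S12 and 6948 from S12 to S13. It was 17389 from S13 to S16, 11885 from S16 to S24, 18454 from S24 to S34 and 12870 from S34 to S41. The stages are not evenly spaced in time, so the counts are not rates. The labels do not name females, so a change of egg batch between stages may add to them. Paternal genes contributed 6919 of the changes from S9 to S10, of which 6777 were rises, and 7044 of those from S13 to S16. DESeq2 called 2723 genes from S3 to S5. Over all 13 stages, 37766 of 37872 genes tested changed, 15143 of them X. tropicalis genes and 22623 X. laevis genes.

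**Figure D5:**
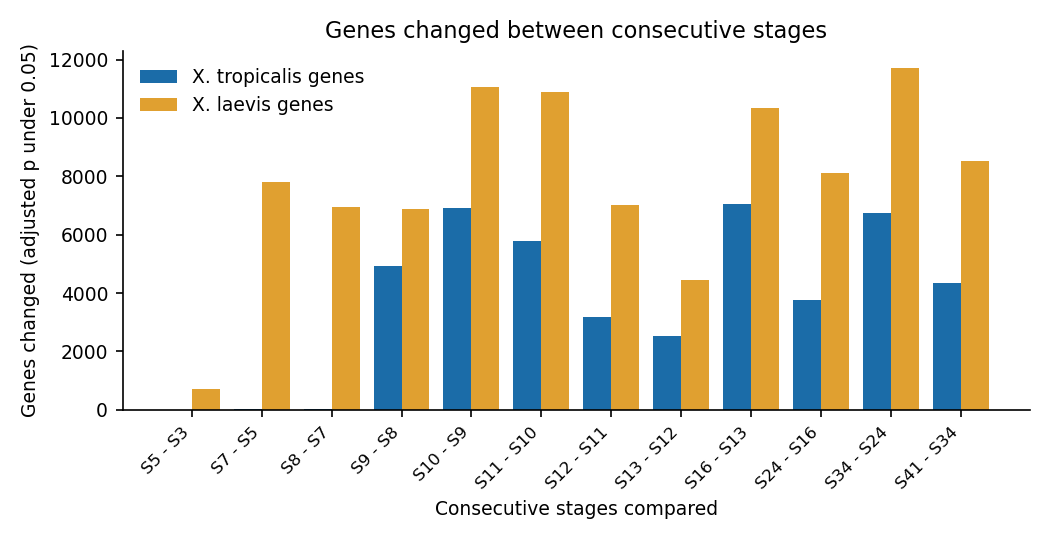
Number of genes past an adjusted p of 0.05 in each of the 12 comparisons of neighbouring stages, by parental gene set. X. tropicalis bars are near 0 up to S8 and reach 6919 from S9 to S10 and 7044 from S13 to S16.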

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

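The fits without X. laevis genes on in 1 S3 or S5 library, and with S8 in place of S7, were chosen only after the results were seen. Of 225 alternative values of the planned results, 207 were within 1.5 times the count, or 1 SD of the value, reported, and 18 were further away. The 207 include paternal shares with 1 library left out. The library that is left always lies within 1 SD of the mean of 2, so those values could not be further away. With a log2 change of at least 1, the genes changed from S3 to S7 went from 9789 to 6438 (X. tropicalis 13 to 3, X. laevis 9776 to 6435), the X. laevis genes changed from S7 to S9 from 10314 to 6019, and the counts of neighbouring stages to 169 (S3 to S5), 4023 (S5 to S7), 3899 (S7 to S8), 6766 (S11 to S12), 3837 (S12 to S13), 7650 (S16 to S24) and 8440 (S34 to S41). The 13 X. tropicalis genes of S3 to S7 became 7 without TMM, 0 by edgeR when scaled within the set (19 at an unadjusted p under 0.05, 16 by DESeq2) and 3 to 12 without single libraries (3 without S3 replicate 1 and 4 without S7 replicate 1). From S7 to S9, 15405 genes became 10250 in a fit of the 4 libraries compared (X. tropicalis 5091 to 1751, of 1774 tested) and 10179 to 13209 without single libraries (X. laevis 6744 to 8241), the lowest without S7 replicate 1. With S8 in place of S7 there were 11802, of them 4936 X. tropicalis and 6866 X. laevis genes. Within the set, 4308 X. tropicalis genes changed from S9 to S12, against 9758. DESeq2 called 2723 genes from S3 to S5, against 699. Leaving out the 1% most abundant genes put the paternal share at S3 at 0.0470%, against 0.274%, at S8 at 0.0414%, against 0.467% and below the 0.0644% of S7, and at S41 at 45.7%, against 44.1%, and leaving out the loci detected at S3 put that at S3 at 0.00132%. At 5 CPM, 766 genes were first detected at S9, against 2155. Of the list tests, 52 passed as reported, 9 with an estimated correlation and 85 with fry, which tests a list against no change and not against other genes. Of the tests called by both camera and fry (44), 9 went in opposite directions. Without X. laevis genes on in 1 S3 or S5 library (25), 9781 genes changed from S3 to S7, 9768 of them X. laevis. Where a library was left out, its partner was assumed to vary like the other stages. For 177 named genes, 2103 of 2121 alternative values kept the call, 18 lost it and 0 changed direction. Those that lost it were bix1.2, nodal3.1, hba4, fga and myl7 with DESeq2, h3c14 without single libraries, klf17 in 8 settings and rap1b when scaled within the set. With the replicate number as a block, 9736, 15295, 24184, 24460 and 21759 genes changed in the 5 contrasts. Replicates with the same number deviated together, at a correlation over 0.1, in 2 of 78 pairs of stages (highest 0.522, lowest -0.0579), so the numbers were not taken to pair samples over the series, though S3 and S5 deviated together. Not run were the parental ratio and the paternal share over genes matched by symbol, because X. laevis genes have no symbols here, the paternal share without mitochondrial genes, because none is named, and settings for normalized values, which do not apply to counts. The cause was not tested for any of these differences.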

Other observations

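All tests in this part were chosen only after the result was seen.

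Some X. laevis genes were on at 2 stages and off at the stage between. With at least 5 CPM in both libraries of each flanking stage and under 0.5 CPM in both libraries between, this held for 45 of 64488 X. laevis cases from S9 to S41 (0.0698%) and 8 of 31989 X. tropicalis cases (0.0250%). The X. laevis share was 2.79 times the X. tropicalis one (lower 95% bound 1.32), but 17 of the 45 cases lay at S11, and without that stage the ratio was 1.84 with a lower bound of 0.838 (Fisher's exact p = 0.16), so a library batch acting on both parental sets alike cannot be told apart from eggs of different females at different stages. Eggs of different females may explain part of it, but the labels do not name females and the hypothesis stays open. Before S9, the 19 X. laevis genes on in S3 replicate 2 alone were higher in S5 replicate 2 in 19 of 19 cases. Those 19 genes were not compared with the 45 cases, and they do not tell females from a library batch. Earlier in the series, 11 of 11285 X. laevis genes on at S5 and S8 were off at S7, and 0 of 18 X. tropicalis ones. With S5, S8 or S9 between, 0 X. laevis genes were on, off and on again.

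A few X. tropicalis counts in early mesendoderm genes were present at S7 and nearly absent at S8, as the list held 9 and 12 counts in the S7 libraries, 0 and 1 at S8 and 0 at S3 and S5. Reads carried over from the S9 libraries are argued against as the whole cause, because the 20 most abundant S9 genes outside the list and the S3 loci held 14 counts at S7 where the list's rate gives 70.2, a ratio with an upper 95% bound of 0.41, which covers counting error only. These 20 genes held 4 counts at S8, so they too had more at S7, and carry-over as part of the cause stays open. Exchanged S7 and S8 labels cannot be told apart from correct ones by X. laevis genes, since 51.5% of 2103 falling ones (1083) were lower at S8 than at S7, and over 13088 genes S8 was nearer than S7 to S9 (mean rank correlation 0.920 against 0.842), the way the labels say, but also nearer to S3 (0.845 against 0.824), the way exchanged labels would have it. The share of counts in the S3 loci, 0.316% at S5, 0.291% at S7, 0.466% at S8 and 0.747% at S9, leans to the labels' order without excluding the other. No biological explanation was tested.

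The S9 replicates differed in paternal share, and 648 of 700 X. tropicalis genes were higher in replicate 1. A single scaling factor for all X. tropicalis genes is argued against, because the median log2 ratio of replicate 1 over replicate 2 was 1.19 over the 700 genes and 0.16 in the 111 lower at S10 than at S9 (quartiles -0.07 and 0.54). A later developmental time of replicate 1 may explain the difference, as genes that were further up by S10 were higher in replicate 1 (r = 0.684 over 700 genes, against -0.189 to 0.140 for replicates of 7 other stages), with eef1a1o at 528 against 171 CPM and hes7.1 at 9.74 against 20.2 CPM. RNA of the S10 libraries mixed into S9 replicate 1 would give this too, and it cannot be told apart, since 87 genes lower at S10 than in S9 replicate 2 had a median log2 ratio of -0.03 (quartiles -0.16 and 0.35). Both stay open, as collection times are not in the labels.

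As a hypothesis, paternal Hox genes may come on in the order of their paralogue numbers. Over 36 genes, Spearman's rho of paralogue number and first stage was 0.487 (permutation p = 0.003). The first gene detected was hoxd1 at S9 and the last was hoxa13 at S34, but the median paralogue was 6.5 at S12 and 5.5 at S16, so the order is loose. First detection depends on level as well as on time, which this test does not separate.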
